A study of Homo sapiens with 6 samples.

How the data were processed

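Gene expression was measured on 6 one-colour arrays of a custom human Agilent design, with cRNA labelled with Cy3 after oligo-dT priming of total RNA, per the labels' protocols. There were 2 arrays of DU-145 cells alone, 2 of DU-145 cells co-cultured with macrophages, 1 of THP-1 macrophages alone and 1 of THP-1 macrophages co-cultured with DU-145, all at 6 hours. Groups and replicate numbers were taken from the labels. All arrays lay on 1 slide and in 1 scan, per the file headers, so neither could be tested as a batch.

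Per the file headers and the submitters' processing notes, spots were read with Agilent Feature Extraction 10.7, and the deposited scanner files give each spot's intensity on a linear scale: a processed, background-subtracted intensity, the mean raw intensity and the local background. The authors also deposited a table of log2 values per probe. Set against the scanner files, each of its columns followed the log2 processed intensity minus a constant near the array's 75th percentile, within 0.01 for at least 99.8% of its 50238 rows; its column medians were -2.23, -2.37, -2.27 and -2.35 for the arrays labelled DU-145 and -3.05 and -2.76 for the THP-1 arrays. That table served as an alternative.

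Each array held 52857 spots, of which 51538 were not controls and belonged to 50238 probes. No spot was saturated, and 231 probes with an outlier flag on any array were left out. Spots of 1 probe were averaged. Probes were named by their accession through a gene table of the assembly GRCh38.p14 for 28595 probes, by current symbol for 2998, by an older symbol for 1176, and kept the file's name for 17469; the assembly was used for names only and no coordinates are given. This gave 30902 gene names, 19614 of them current symbols, 9317 with more than 1 probe. The probe that was brightest by its mean over all 6 arrays stood for a gene, and other probes are given where they disagree.

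Values are log2 of the processed intensity minus the array's 75th percentile over non-control probes. This scaling had been fixed before the data were examined and was kept although under 50% of spots were well above background on the arrays labelled DU-145; the percentile over probes detected on all arrays was added as an alternative. Genes well above background on at least 2 of the 4 arrays labelled DU-145 were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), 14822 in all, 10869 of them with a current symbol. Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. Between the THP-1 arrays, genes well above background on at least 1 array were compared by size, with no test, and each list's median was placed among 10000 random lists of the same size matched on brightness; lists in the outer 2.5% on either side were counted as outside. Where a probe was not well above background on any array of a group, a fold between group means is given as a lower bound. Each array of that group then counts with the higher of the probe's own value and the array's lowest well-above-background signal.

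26 gene lists were fixed before the data were examined, 25 of which had at least 5 tested members on the arrays labelled DU-145. So was the rule for naming genes: on the arrays labelled DU-145, the 12 genes per direction past the threshold with the largest change, filled with the lowest unadjusted p where fewer passed (here all 24), among genes with a symbol and well above background on all 4 arrays, plus CTTN, SH3PXD2A, MMP14, MMP9, PLAU and PLAUR always; on the THP-1 arrays, the 10 largest positive and 10 largest negative differences among genes with a symbol, well above background on both arrays and with the brighter signal above the median of its array's detected genes, and the 4 largest in the direction of each list outside the random range. Other members of the fixed lists are named as examples after their values were seen. 1 gene that the rule names is not reported here. The 60 genes taken to be used by every human cell were listed from textbook knowledge. This was done after the arrays labelled DU-145 had been seen to lack abundant transcripts. Whether DU-145 cells express each of the 60 was not checked. The genes were read by the probe brightest on THP-1 alone and, beside it, by any probe.

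The replicate numbers are shared between the groups labelled DU-145, but no label says that they mark a shared culture, so they were not used to pair arrays. Replicate arrays did not hold identical values: the SD of the log2 difference was 0.465 for the arrays labelled DU-145 alone and 0.373 for the co-cultured ones, over 12373 genes. The alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50, the authors' table, the mean of all probes, other filters and floors, outlier spots kept, trended and unmoderated variance, a replicate block, and each array labelled DU-145 left out in turn. Steps were tested on simulated data: with 200 of 14822 genes changed, limma called 51.2% of genes changed 4-fold and made 4.6 false calls per simulation on average. Odds ratios and shares of probes were computed with Python 3.11.15, SciPy 1.17.1 and statsmodels 0.14.6, and figures with matplotlib 3.10.9.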

Results

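The series asks, by its title, what part macrophages play in the formation of invadopodia, the actin-rich protrusions with which invasive cells degrade matrix. Expression was measured on 6 one-colour Agilent arrays, all after 6 hours of culture and all on 1 slide. 2 arrays were labelled DU-145 alone, a human prostate carcinoma line, and 2 were labelled DU-145 co-cultured with macrophages. 1 array was labelled THP-1 macrophages alone and 1 THP-1 macrophages co-cultured with DU-145; THP-1 is a human monocytic leukaemia line used as a macrophage model. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical. The THP-1 groups had 1 array each, so their differences have no replicate check and no test. The number of arrays limits the precision.

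The arrays labelled DU-145 were dimmer than the THP-1 arrays, and many probes of abundant human transcripts read at background on them while others were bright. The 75th percentile of the processed signal was 27.1 and 24.1 on the arrays labelled DU-145 alone and 25.9 and 27.3 on the co-cultured ones, against 325 on THP-1 alone and 646 on co-cultured THP-1. Spots well above background made up 38.3% and 35.2% of non-control spots on the arrays alone, 39.3% and 39.2% on the co-cultured arrays, and 65.4% and 73.8% on the THP-1 arrays. Signals of the added control RNAs rose with their known amounts on all 6 arrays, with log-log slopes between 0.945 and 1.01. The epithelial genes CDH1 (E-cadherin), EPCAM and DSP (desmoplakin), with 1 probe each, were not well above background on any of the 4 arrays labelled DU-145. Keratin 8 (KRT8) was, at 216 ± 21.1 alone and 213 ± 11.3 co-cultured (SD, n = 2 each). From textbook knowledge, 60 genes were taken to be used by every human cell, without a check that DU-145 cells express each of them. They were read by the probe brightest on THP-1 alone. By that probe all 60 were well above background on both THP-1 arrays and 45 on all 4 arrays labelled DU-145, which is 75% with an exact 95% interval of 62.1% to 85.3%; 10 were well above background on none of the 4. With a gene counted if any of its probes was well above background on all 4, there were 53 genes, 88.3% with an exact 95% interval of 77.4% to 95.2%, and the 4 with no such probe on any array were TUBA1B, LDHB, PGAM1 and MDH2. Probes of 1 gene disagreed: for the cyclophilin gene PPIA, 1 probe gave 32384 on THP-1 alone and 2.48 ± 0.228 on the arrays labelled DU-145 alone (SD, n = 2), and another gave 10755 and 29550 ± 7047 (SD, n = 2). For annexin A2 (ANXA2), 1 probe gave 42407 and 3.14 ± 0.526 and another 20394 and 225 ± 76.2 (SD, n = 2 each). Other genes of the same list were as bright as on THP-1: GAPDH, a glycolytic enzyme, gave 65233 on THP-1 alone and 102970 ± 12532 on DU-145 alone (SD, n = 2). By the probe brightest there, THP-1 alone was over 64-fold brighter than the mean of the 4 arrays for 29 of the 60 genes and under 2-fold brighter for 19. By each of its probes well above background on THP-1 alone, 17 of the 60 genes were over 64-fold dimmer on the arrays labelled DU-145. Only 45 of the 60 genes had several probes. These folds are of unscaled signals, so they include the difference in brightness between the arrays.

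**Figure D1:**
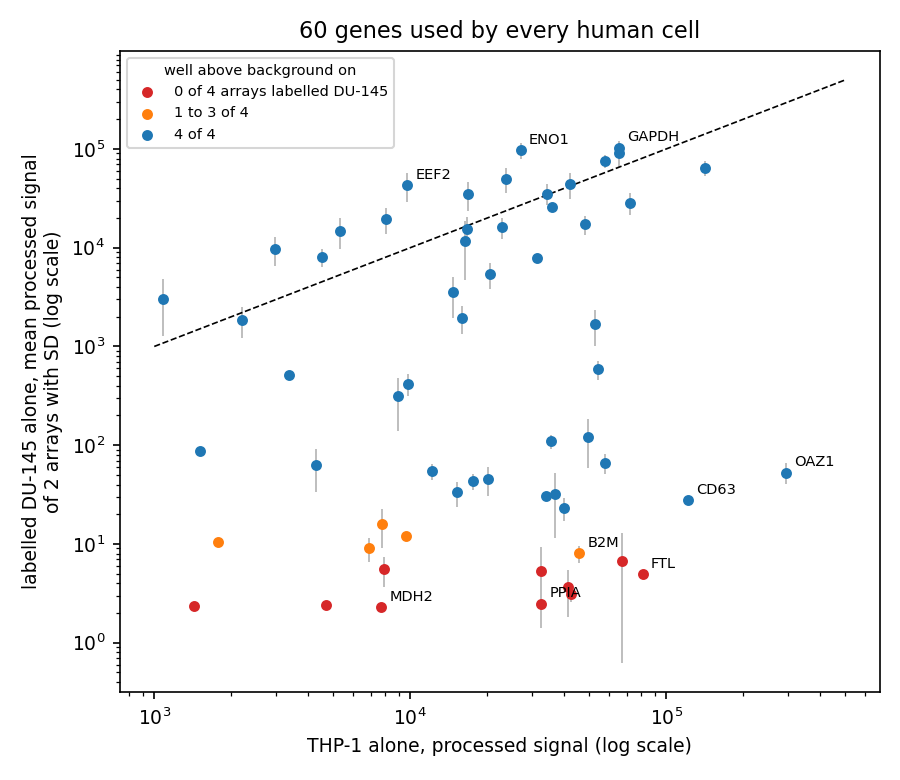
Processed signal of 60 genes taken to be used by every human cell, each by its probe brightest on THP-1 alone. The x axis (log scale) is the THP-1 alone array. The y axis (log scale) is the mean of the 2 arrays labelled DU-145 alone, with SD bars. Colours give the number of arrays labelled DU-145 on which the probe was well above background. The dashed line marks equal signal, and the probes of FTL and PPIA lie at background on the y axis while GAPDH and ENO1 lie above the line.

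The THP-1 arrays carried the myeloid genes their label names. Of 38 myeloid markers on the array, 36 were well above background on THP-1 alone and 37 on co-cultured THP-1, against 19 and 19 on the arrays labelled DU-145 alone and 21 and 20 on the co-cultured ones. CSF1R, the receptor for the macrophage growth factor CSF1, gave 32816 on THP-1 alone and 41.0 ± 0.413 on DU-145 alone (SD, n = 2). After scaling, the myeloid markers were higher on THP-1 alone than on the arrays labelled DU-145 alone by a median of 3.64 on the log2 scale, and by 2.68 to 5.39 under other settings. Of 27 epithelial markers, 12 and 11 were well above background on the arrays labelled DU-145 alone and 12 on THP-1 alone. Of 12 fibroblast markers on the array, 8 were well above background on both THP-1 arrays, among them FAP at 2184 on THP-1 alone and 1746 on co-cultured THP-1. Across the 11399 genes well above background on all 6 arrays, log2 values correlated between arrays labelled DU-145 with r from 0.987 to 0.991 and between the 2 THP-1 arrays with r = 0.958. Between an array labelled DU-145 and a THP-1 array, r lay between 0.567 and 0.579. These correlations are across genes, which are not independent replicates.

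The first comparison asks which genes of the tumour cells changed after 6 hours with macrophages. None of the 14822 genes tested rose or fell on the co-cultured arrays labelled DU-145: limma with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower, and the lowest adjusted p was 0.786. At an unadjusted p under 0.05 there were 883 genes, 378 higher and 505 lower, where chance gives 741.1. Both co-cultured arrays lay beyond both arrays alone for 38.3% of genes, against 33.3% by chance. The 2 groups did not stand apart as wholes: the 2 arrays alone differed by at least 2-fold at 8.98% of genes and the 2 co-cultured arrays at 6.93%, while pairs across the groups differed at 7.84% to 9.18%. The median 95% interval of a gene's log2 difference reached 0.63 to each side, a 1.54-fold change. In simulated data with this spread, 0.672% of genes changed 2-fold, 51.2% of those changed 4-fold and 88.5% of those changed 8-fold were called, so smaller changes were not detectable with these arrays.

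Among genes with a symbol and well above background on all 4 arrays, the 24 with the lowest unadjusted p-values, 12 per direction, had log2 differences from -1.54 to 0.95, and none passed the adjusted threshold. Among the 12 with a higher mean on the co-cultured arrays, GABBR1, a subunit of the GABA-B receptor, differed by 0.95 (SE 0.22), ABHD1 by 0.93 (0.04 by its other probe) and EPHB6, an Eph receptor without kinase activity, by 0.90. Hepatocyte growth factor (HGF) differed by 0.83, the melanocortin receptor MC1R by 0.77, and MAP7D3, TSG1, TRIM29, OR4K13, CARHSP1, SYT3 and ZNF157 by 0.75 to 0.88 (OR4K13 by 0.61 with its other probe). Among the 12 with a lower mean, the glucose transporter SLC2A1 differed by -1.09 (SE 0.25), the chemokine CCL3 by -1.04, the membrane-binding protein CPNE3 by -1.45 and the pigment-cell transporter SLC45A2 by -1.54. CMIP differed by -1.33 (-0.30 by its other probe), ZNF608 by -1.27, EMC1 by -1.12, the glycogen phosphatase EPM2A by -1.04, and ZBTB20, OR8D1, CIART and ASXL1 by -0.96 to -0.92; the other probe of CIART gave 0.92. The adjusted p of each of these 24 genes was 0.786. Some of the falls ended near the detection limit. Scaled co-cultured means were -1.26 for SLC45A2, -1.23 for CCL3 and -1.17 for ZBTB20, against 5.49 for SLC2A1. The urokinase receptor gene PLAUR, not well above background on the arrays alone, had a mean of -1.37 there.

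Genes of invadopodia were tested as a group fixed before the data were examined. Of its 30 members, 24 were tested on the arrays labelled DU-145 and 0 passed over all genes tested; 17 had lower and 7 higher means in co-culture. Adjusted over the list alone, 1 passed: ADAM12, a metalloprotease of the cell surface, had a log2 difference of -1.57 (SE 0.28, limma adjusted p = 0.0369 over the list and 0.786 over all genes), and was named after its value was seen; it was well above background on 1 of the 2 co-cultured arrays. SH3PXD2B, which encodes the scaffold TKS4, was the only other member with an unadjusted p under 0.05 and differed the other way, by 1.07 (SE 0.35, limma adjusted p = 0.292 over the list and 0.786 over all genes), with 1 of the 2 arrays alone well above background. Cortactin (CTTN), an actin-binding protein of the invadopodium core, differed by -0.58 (SE 0.24, limma adjusted p = 0.786). SH3PXD2A, which encodes the scaffold TKS5, differed by -0.31 (SE 0.26), the gelatinase MMP9 by 0.31 (SE 0.23) and the protease urokinase (PLAU) by -0.43 (SE 0.38), with limma adjusted p-values from 0.829 to 0.842. The urokinase receptor PLAUR was not well above background on the arrays alone, and its mean was at least 1.24-fold higher in co-culture (limma adjusted p = 0.820). Its co-cultured arrays did not both lie above both arrays alone. The membrane protease MMP14 was not well above background on any of these 4 arrays, at 8.81 ± 0.212 alone and 6.57 ± 1.23 co-cultured (SD, n = 2 each), and was not tested. The difference of SH3PXD2A was 0.86 by its other probe and 0.27 with the mean of all its probes, and that of PLAU was 0.086 without co-cultured replicate 2.

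**Figure D2:**
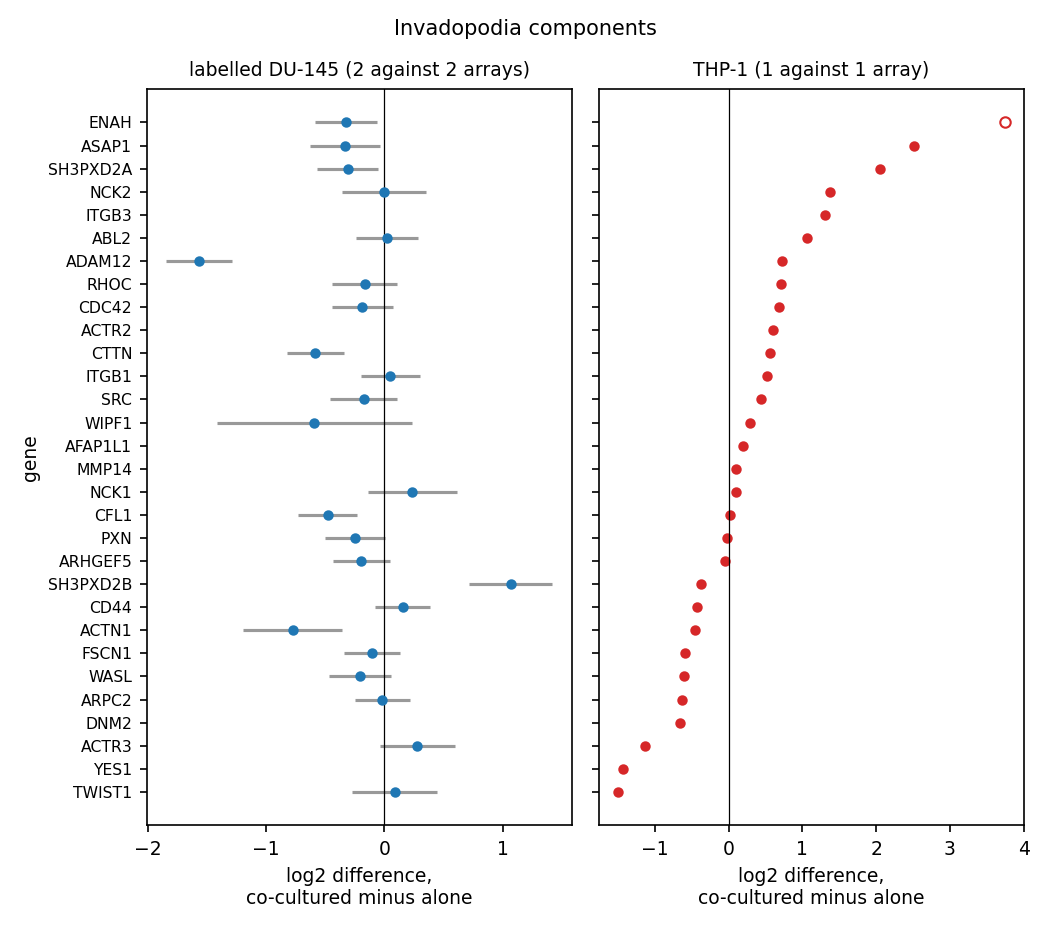
Log2 differences, co-cultured minus alone (x axes), of invadopodia genes (y axis) on the arrays labelled DU-145 (left, 2 against 2 arrays, bars are standard errors) and on the THP-1 arrays (right, 1 against 1). Genes without a left-hand point were not tested there, the open circle marks ENAH, which was not well above background on THP-1 alone, and ADAM12 at -1.57 lies furthest from 0 on the left.

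None of the 25 lists tested on these arrays shifted by limma's camera test, whose lowest adjusted p was 0.361; the lowest was 0.882 with an estimated correlation and 0.907 by fry. 3 lists had an unadjusted camera p under 0.05. They were oxidative phosphorylation, with 17 of 18 members lower in co-culture and a median of -0.19, hypoxia targets, with 11 of 15 lower and a median of -0.44, and epithelial markers, with 8 of 12 higher and a median of 0.16. Of the hypoxia targets, DDIT4, an inhibitor of mTORC1, differed by -1.29. BNIP3, a mitochondrial death-related protein, was not well above background on the co-cultured arrays and was at least 1.23-fold brighter alone, and PFKFB3, a regulator of glycolysis, was not well above background on the arrays alone and was at least 1.31-fold brighter in co-culture; neither passed the test. Matrix proteases and inhibitors had a median of -0.14 over 19 genes. The medians of the other lists were -0.15 for NF-kB targets, 0.02 for cytokines and chemokines, 0.10 for type I interferon targets, -0.02 for interferon gamma targets and antigen presentation, -0.10 for immediate early genes and -0.07 for mesenchymal genes. Mitosis genes had a median of -0.26, DNA replication genes -0.04, unfolded protein and amino acid response genes -0.12, cholesterol synthesis genes -0.02, NRF2 and oxidative stress targets -0.18, heat shock proteins -0.13, p53 targets 0.02 and TGF-beta targets -0.01. The EGF and CSF1 paracrine loop had a median of 0.04, genes of classically activated (M1) macrophages -0.09, of alternatively activated (M2) macrophages 0.05, myeloid markers 0.01, endothelial markers 0.02 and lymphocyte markers -0.33. Fibroblast markers had under 5 tested members. Median, mean and camera direction were not all alike for 10 of the 25 lists; median and mean were opposite in sign for cytokines and chemokines, type I interferon targets, DNA replication, cholesterol synthesis, p53 targets, the paracrine loop and M1 genes.

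The second comparison asks which genes of the macrophages differed after 6 hours with tumour cells. Cell division genes were lower on the co-cultured THP-1 array and genes of low oxygen and heat shock were higher. These are scaled values, relative to each array's 75th percentile, which was 325 on THP-1 alone and 646 on co-cultured THP-1. Of 24200 genes measured, 3774 were at least 2-fold higher and 2695 at least 2-fold lower, 26.7% together, against 6.93% and 8.98% between the replicate pairs labelled DU-145, which are dimmer arrays. With normexp background correction 1016 genes were higher and 2013 lower, so the number and its balance depend on the processing, and single differences describe these 2 arrays only.

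Of 25 mitosis genes, 13 were at least 2-fold lower and 0 at least 2-fold higher, and 23 had a negative difference. Their median was -1.001, below all of 10000 random lists of the same size and brightness. Random lists hold genes that need not move together, so their range is too narrow for lists whose members do. Percentiles here and below therefore describe positions and are not tests. On the arrays labelled DU-145 the estimated correlation between members was 0.36 for mitosis genes, 0.35 for hypoxia targets and 0.53 for heat shock proteins. It was 0.12 for DNA replication genes and -0.04 for type I interferon targets. NUSAP1, a spindle protein, differed by -2.69, DLGAP5, which stabilises spindle microtubules, by -1.95, the kinetochore gene CENPF by -1.82 (0.03 by its other probe) and the ubiquitin-conjugating enzyme UBE2C of the anaphase-promoting complex by -1.81. Of 26 DNA replication genes, 7 were at least 2-fold lower and 0 higher, with a median of -0.60 at percentile 0.42 of the random lists. E2F1, a transcription factor of S-phase entry, differed by -1.96, the ribonucleotide reductase subunit RRM1 by -1.51, MCM10 by -1.39 and the polymerase subunit POLA1 by -1.33.

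Type I interferon targets were lower as a group as well, with a median of -0.55 at percentile 0.43, 7 of 30 at least 2-fold lower and 1 at least 2-fold higher. IFI44 differed by -2.23, IFIT2 by -1.95 (0.89 by its other probe), the antiviral RNA-binding protein IFIT1 by -1.78 and the virus tether BST2 by -1.48, while OAS3 was higher by 1.23. Fibroblast markers, measured for 8 genes, had a median of -0.90 at percentile 0.67, with all 8 lower after scaling. FBN1, which encodes fibrillin, differed by -1.97, FAP by -1.31, THY1 by -0.99 and COL6A3 by -0.91 (2.07 by its other probe). Before scaling, FBN1 went from 521 on THP-1 alone to 264 in co-culture and FAP from 2184.5 to 1745.9. THY1 went from 1205.1 to 1206.7 and COL6A3 from 1279.5 to 1352.3, so these signals fell only relative to a brighter array. The fibroblast list lay inside the random range, at percentile 24.4, with the mean of all probes.

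Hypoxia targets had a median of 0.44 at percentile 99.97, with 7 of 25 at least 2-fold higher as measured and 0 at least 2-fold lower; the 7 include CA9, for which the bound against background does not support a higher level. With signals raised to the lowest well-above-background signal, the median of the hypoxia targets was 0.29. The glycolytic enzyme PGK1 differed by 1.44 (0.27 by the median of its other probes), the mitophagy receptor BNIP3L by 1.35 (-0.24 by its other probe), MXI1 by 1.15 and the pyruvate dehydrogenase kinase PDK1 by 1.13. EGLN3, an oxygen-sensing hydroxylase, was not well above background on THP-1 alone and was at least 3.19-fold brighter in co-culture; CA9 was not well above background on THP-1 alone either, and no fold is given. VEGFA, the angiogenic factor counted among the cytokines, differed by 1.76. Heat shock proteins had a median of 0.38 at percentile 99.82, with 3 of 17 at least 2-fold higher and 0 lower. Over 11 other settings the median ran from 0.15 to 0.75 for hypoxia targets and from 0.09 to 0.72 for heat shock proteins, so the size depends on the processing. The co-chaperone BAG3 differed by 1.51, HSPA1A by 1.46 (0.55 by its other probes), HSPA1B by 1.00 and HSPA4L by 0.94. Immediate early genes (median 0.14, percentile 97.66) and oxidative phosphorylation (median 0.05, percentile 98.25) lay just above the range of random lists, each in 8 of 11 other settings. With median scaling, which moves every gene by the same amount and no list's place among random lists, their medians were -0.15 and -0.25. Of the immediate early genes, PHLDA1 differed by 1.19 (0.75 by its other probes), KLF4 by 1.08, FOSL1 by 0.92 (0.67 by its other probe) and SPRY4 by 0.83; of the oxidative phosphorylation genes, NDUFB5 differed by 1.29, ATP5F1B by 0.85 and COX7B by 0.65.

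**Figure D3:**
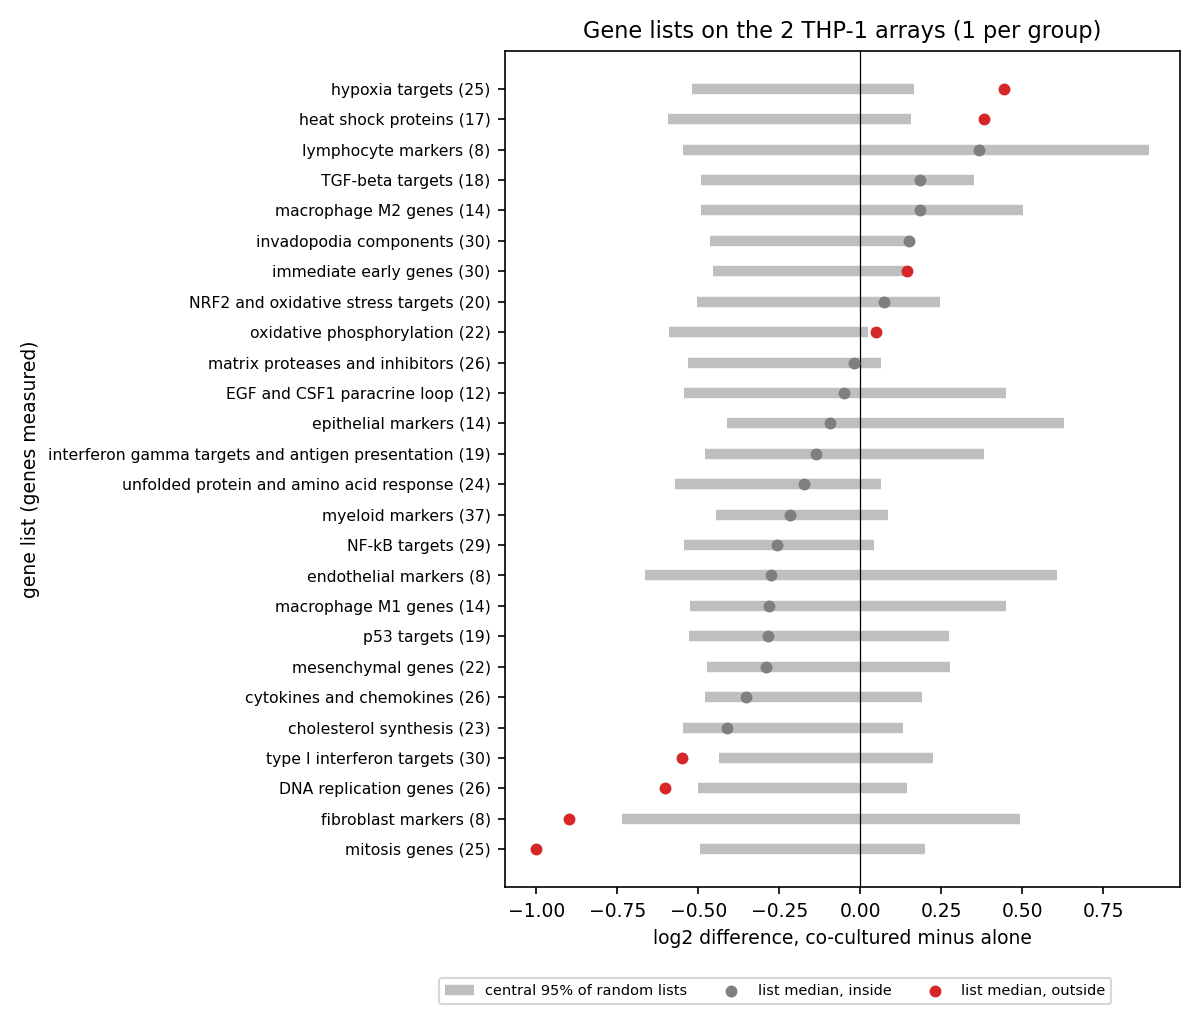
Median log2 difference, co-cultured minus alone (x axis), of each of 26 gene lists (y axis, number of genes measured in brackets) between the 2 THP-1 arrays, with 1 array per group. Grey bars span the central 95% of 10000 random lists of the same size and brightness, and 8 lists lie outside, from mitosis genes at -1.001 to hypoxia targets at 0.44. The bars are too narrow for lists whose members move together.

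Invadopodia genes lay inside the range of random lists on the THP-1 arrays, with a median of 0.15 at percentile 97.19. In 3 of 11 other settings, quantile normalization and normexp among them, the list lay above that range (percentiles 91.02 to 99.43 over the 11). Scalings that move every gene alike put its median at -0.15 and 0.39 and leave its percentile as it is. Of 30 genes, 6 were at least 2-fold higher and 3 at least 2-fold lower. The Arf GTPase-activating protein ASAP1 differed by 2.51, SH3PXD2A by 2.05, the adaptor NCK2 by 1.37, the integrin subunit ITGB3 by 1.30 and the kinase ABL2 by 1.07. ENAH, an actin regulator, was not well above background on THP-1 alone and was at least 7.02-fold brighter in co-culture. TWIST1 differed by -1.49, the kinase YES1 by -1.44 and the Arp2/3 subunit ACTR3 by -1.13. CTTN differed by 0.56, MMP14 by 0.10, MMP9 by -0.61, PLAU by -1.11 and PLAUR by 0.75. Matrix proteases and inhibitors had a median of -0.02 at percentile 92.34; they lay above the random range in 2 of 11 other settings, with medians from -0.32 to 0.36 and percentiles from 16.22 to 99.525. The collagenase MMP1 gave 269280 on THP-1 alone and 365190 on co-cultured THP-1, a log2 difference of -0.55 after scaling.

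The 10 largest positive and 10 largest negative differences between the THP-1 arrays, among bright genes well above background on both, were taken by size alone. The positive ones were in MED18, a Mediator subunit, at 4.41, TMEM95 at 4.27, the endoplasmic reticulum stress sensor ERN1 at 4.23, the histone gene H4C5 at 3.84, the transcription factor subunits TAF13 and GTF2A1 at 3.76 and 3.52, BZW1 at 3.59, the EGF receptor ligand EREG at 3.53, OR9K2 at 3.49 and the receptor GIPR at 3.48. The negative ones were in the endocytic receptor LRP1, at -13.26 from a signal of 706070 to 143, the transcription factor NFE2L1 at -8.84, LCE2D at -6.16, CMIP at -4.08, SCRT2 at -3.82, CFAP65 at -3.71, DAZL at -3.64, the kinetochore gene NUF2 at -3.38, KRTAP4-1 at -3.36 and FOXE1 at -3.34. Of these 20 genes, 9 had another measured probe, and for 7 of the 9 the other probes' median was opposite in sign or within 1 of 0. For NFE2L1 it was -0.48, for ERN1 -0.05, for BZW1 -0.09, for EREG -1.16, for GIPR 0.22, for CMIP 0.41 and for FOXE1 0.55.

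The remaining lists on the THP-1 arrays lay inside their random ranges. Myeloid markers had a median of -0.22, NF-kB targets -0.26, cytokines and chemokines -0.35, interferon gamma targets and antigen presentation -0.14, M1 genes -0.28 and M2 genes 0.18. Mesenchymal genes had a median of -0.29, unfolded protein and amino acid response genes -0.18, cholesterol synthesis genes -0.41, NRF2 and oxidative stress targets 0.07, p53 targets -0.28, TGF-beta targets 0.19 and the EGF and CSF1 paracrine loop -0.05. Markers of other cell types had medians of -0.10 for epithelial, -0.27 for endothelial and 0.37 for lymphocyte genes. Median and mean were opposite in sign for matrix proteases, the paracrine loop and epithelial markers.

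By the median of myeloid markers, no macrophage signal was detected on the co-cultured arrays labelled DU-145. Over 22 myeloid markers at least 8-fold brighter on THP-1 alone, the co-cultured arrays stood at -0.0244% and -0.107% of the THP-1 signal above the mean of the arrays alone, which themselves stood at -0.0538% and 0.0538%. A share of 5% mixed in silico was recovered as 4.95%. That mix was made in the same scaled signals, so it checks the calculation and not the recovery of mixed RNA. The shares are of scaled signal and not of RNA. Many probes bright on THP-1 read at background on the arrays labelled DU-145, for a reason left undecided. If that reason also dimmed macrophage RNA there, these shares would miss it. The reverse, RNA of the tumour cells on the co-cultured THP-1 array, was not measured. Genes higher on that array are therefore not shown to have risen in the macrophages. Between the co-culture differences on the arrays labelled DU-145 and on the THP-1 arrays, Pearson's r was 0.0691 and Spearman's rho 0.0632 across 12896 genes, which are not independent replicates. With no gene past the threshold on the arrays labelled DU-145, a value near 0 says nothing on whether responses were shared.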

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

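The direction in which co-culture moved a result on both arrays labelled DU-145 (against the mean of the arrays alone) was compared with the direction on the THP-1 array; these differences were not tested, since THP-1 has 1 array per group. Of 25 lists, 11 moved one way on both arrays labelled DU-145 and the other way on THP-1, where chance alone gives 30.4% for normal errors, since both arrays are set against the same mean. The medians run over the members measured on each kind of array, which differ (15 and 30 interferon targets, for example). The THP-1 direction of invadopodia, immediate early, NRF2, oxidative phosphorylation, epithelial, lymphocyte and cytokine lists turned under at least 1 other setting. The value given is the mean of the 2 arrays labelled DU-145 minus THP-1, on the log2 scale. Hypoxia targets stood at -0.81, with -0.50 and -0.23 on the arrays labelled DU-145 and 0.44 on THP-1. Type I interferon targets stood at 0.65, lymphocyte markers at -0.61, heat shock proteins at -0.53, cytokines and chemokines at 0.40, endothelial markers at 0.32, invadopodia components at -0.28, oxidative phosphorylation at -0.27, NRF2 and oxidative stress targets at -0.24, immediate early genes at -0.23 and epithelial markers at 0.22.

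Of 26 named genes measured on both kinds of array, 12 went opposite ways. Their differences, computed in the same manner, were -2.79 for EPM2A, -2.36 for SH3PXD2A, -1.85 for CPNE3, -1.46 for OR8D1 and -1.14 for CTTN, which were lower in co-culture on the arrays labelled DU-145 and higher on THP-1. For SH3PXD2A the other probe on the arrays labelled DU-145 gave 0.86 and the mean of all its probes 0.27, so its direction there depends on the probe. They were 1.52 for ABHD1, 1.43 for HGF, 1.35 for CARHSP1, 1.25 for EPHB6, 1.20 for MC1R, 0.98 for SYT3 and 0.92 for MMP9, which went the other way. Apart from CTTN, SH3PXD2A and MMP9, these genes were named for a low p on the arrays labelled DU-145, so their direction there was selected. A THP-1 direction unrelated to it would be opposite about as often as not, so 12 of 26 is near chance.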

How the results depend on the processing

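Results were recomputed under 26 alternative settings, 4 of them chosen after seeing the data (the percentile over probes detected on all arrays, uneven spots left out, the crossed pairing and no scaling between arrays). With all arrays, every setting run gave 0 genes higher and 0 lower on the co-cultured arrays labelled DU-145, with a lowest limma adjusted p from 0.179 to 0.891, and 0 lists, with a lowest adjusted p from 0.117 to 0.907. Leaving out 1 array in turn gave 0 to 2 genes higher. The 2 came without DU-145 co-cultured replicate 2 (lowest limma adjusted p 1.95e-05) and were NOSTRIN and ATOX1, named after their values were seen. NOSTRIN read 75358 on co-cultured replicate 1 and 12.1 on replicate 2, and ATOX1 394 and 22.1; the lone co-cultured array is assumed there to vary like the others. Genes at an unadjusted p under 0.05 numbered 883 in the fit as designed, 1821 with no filter on dim probes, 1703 without DU-145 alone replicate 2 and 502 without co-cultured replicate 2. Same-numbered arrays deviated oppositely (r = -0.144 across genes); the replicate block gave 0 calls and 736 genes at an unadjusted p under 0.05, and the crossed pairing 0 calls and 1137. The slide as a block was not run, since all arrays lay on 1 slide. Of 571 values of named genes on the arrays labelled DU-145, 3 reversed: CIART was 0.12 with normexp, SH3PXD2A 0.27 with the mean of all probes, and PLAU ranged from -0.95 to 0.086 with 1 array left out (positive, at 0.086, without co-cultured replicate 2); the cause was not tested.

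Genes at least 2-fold higher on co-cultured THP-1 numbered 3774 as designed, 2302 with quantile normalization, 1016 with normexp and 2213 when both arrays had to be well above background, which tests fewer genes. Genes at least 2-fold lower numbered 2695, and 4535 with median scaling. Higher genes made up 58.3% of the 2-fold genes as designed, 47.6% with quantile normalization, 36.8% with median scaling, 33.5% with normexp and 73.4% with the percentile over probes detected on all arrays. The median of all genes stood at 0.02 as designed and moved to -0.28 with median scaling, -0.30 with normexp and 0.26 with that percentile, so the balance of higher and lower genes depends on the scaling and on the background correction. Of the 8 lists outside the random range, 5 lay outside with the mean of all probes. Mitosis, DNA replication, type I interferon, hypoxia and heat shock lists kept their side of the range in all 11 settings, immediate early genes and oxidative phosphorylation in 8 and fibroblast markers in 9. Of these settings, median scaling and the percentile over probes detected on all arrays move every gene alike. They cannot change a list's place and are no check of it. Of 572 values of named THP-1 genes, 48 moved by more than 0.546 on the log2 scale. That is 1 SD of a replicate difference, which only the arrays labelled DU-145 provide. Among the 572 values, 3 changed sign: CA9 with normexp and with a floor, and COL6A3 with the mean of all probes. The myeloid share was 0.00483% with quantile normalization, -0.167% with the mean of all probes, -0.277% with a floor, 0.0123% with the percentile over probes detected on all arrays, -0.144% over all genes at least 32-fold brighter and -0.00491% with no scaling. The correlation between the co-culture differences on the arrays labelled DU-145 and on the THP-1 arrays stayed between 0.0379 and 0.0899. Low signal over background on the arrays labelled DU-145 limits what they can show: 12373 of the 14822 genes tested were well above background on all 4.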

Other observations

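Chosen after results were seen were the comparisons of probes within genes, their adjustment for GC content and THP-1 signal, all tests on genes used by every human cell, and the test of cycling macrophages; the odds ratios over all bright probes, the quantile normalization test and the pixel test were set beforehand. Smaller groups of genes on the THP-1 arrays, named after their values were seen, had large differences inside lists that did not stand apart. The neutrophil chemokine CXCL5 differed by -2.89, the costimulatory molecule CD86 by -2.70 and the interferon-induced chemokine CXCL10 by -2.15 on the co-cultured array. The decoy receptor IL1R2 differed by 2.04, and the cytokines LIF and IL33 by 1.24 and 1.31. These come from 1 array per group.

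Many probes of abundant human transcripts read at background on the arrays labelled DU-145. The tests set beforehand, over 16093 probes bright on THP-1, did not decide: probes holding a poly(A) signal had an odds ratio of detection of 1.05 (95% interval 0.918 to 1.19) at like GC content and THP-1 signal, where degraded RNA needed a value above 1 and RNA of another organism one below 1 together with an odds ratio above 1 for probes with a reading frame free of stop codons, which was 1.65 (1.495 to 1.81). Within genes, counting those with only 1 of 2 kinds of probe detected, the poly(A) probe was the detected one in 34.8% (28.3% to 41.8%) and the open-frame probe in 71.5% (66.5% to 76.2%); poly(A) probes had 4.59 fewer G and C bases on average, and at equal GC content and THP-1 signal the shares were 44.3% (34.1% to 54.9%), which does not decide on degradation, and 67.2% (60.7% to 73.1%). Degraded human RNA therefore stays open, since probe positions within transcripts were not measured, and so does, as a hypothesis found and tested on the same data, RNA of another organism, which may bind the conserved coding part of human probes and for which the 67.2% is the share it needs, above 50%. A stop-free frame was present in 13415 of the 16093 probes and coding position was not measured. The 67.2% therefore does not show that coding sequence was the part detected. Detection alone left RNA of another human cell type undecided. Of genes taken to be used by every human cell, 75% were detected by their brightest THP-1 probe and 88.3% by any probe. The upper exact 95% bound of the latter was 95.2%, above the 90% set for a human cell. By every probe, 28.3% of these genes (17.5% to 41.4%), TUBA1B and OAZ1 among them, were over 64-fold dimmer than on THP-1 alone. For intact RNA of a human cell at most 5% was allowed. The folds are of unscaled signals, and the 75th percentile was 325 on THP-1 alone against 24.1 to 27.3 on the arrays labelled DU-145. The gene list, the 64-fold limit and the 5% were set after these arrays were seen. Expression of each listed gene in DU-145 cells was not checked either. The test therefore does not decide on intact human RNA.

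Mitosis genes were lower on the co-cultured THP-1 array. Their median was -1.01 after quantile normalization, so unlike signal distributions of the 2 arrays do not account for a fall relative to other genes. Quantile normalization removes overall brightness just as the scaling does, so it does not decide on brightness itself. The 75th percentile was 325 on THP-1 alone and 646 on co-cultured THP-1, and the fall is relative to that brighter array. Fewer cycling macrophages in co-culture may account for the lower mitosis genes. The DNA replication list, which shares no gene with the mitosis list, lay at percentile 0.42 of random lists. This test was chosen after results were seen. Both lists come from the same 2 arrays and the same scaling, so the second is not independent support. With 1 array per group, fewer cycling macrophages remain a hypothesis. A difference between the 2 cultures that has nothing to do with the tumour cells was not tested.

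The largest differences between the 2 THP-1 arrays, such as LRP1 at -13.26, came with smooth spots. Of the 20 genes, 0 had a pixel SD above 0.5 of the mean on the brighter array. Their pixel SDs there were 0.0635 to 0.243 of the mean, against a median of 0.177 for all genes. The count of 0 cannot decide on uneven spots, since 39 of 24200 genes, 0.161%, passed that limit and chance gives about 0 among 20 genes. Their other probes often disagreed, no further technical explanation was tested, and the co-culture itself stays open as an untested one.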
